A study of Homo sapiens with 20 samples.

How the data were processed

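Gene expression was measured in HuES6 human embryonic stem cells on Illumina bead arrays, 1 array for each of 20 combinations of 5 BMP4 and 4 CHIR doses. Per the labels' protocols, the doses were given in the first 24 hours on Matrigel with 10 ng/ml FGF2, the WNT inhibitor IWP-2 (2 µM) was given on days 2 and 3, and cells were harvested on day 14. RNA was purified with Qiagen RNeasy and labelled with the Illumina TotalPrep kit, per the labels. A time-point tag of each sample gives a day between 0 and 8, against 14 days in the sample titles and protocol. The titles were followed, and the tag entered as an alternative covariate.

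The authors deposited the signal intensity of each of 47323 probes, neither background-subtracted nor scaled between arrays, exported from GenomeStudio per the submitters' processing notes. Per the file headers, each signal is followed by a detection p-value, which takes steps of 1 in 770. The authors also deposited a table of processed intensity values on a linear scale, from -8.863 to 15136, with a median of 5.20 on every array. Its order of probes within an array had a rank correlation of 1 with the deposited signals of the same array and at most 0.905 with another. How it was normalized is not given in the sources used here, so it served as an alternative.

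Background correction and quantile normalization were done with neqc (limma 3.58.1, R 4.3.3) with an offset of 16, using the detection p-values to estimate the background. Probe names came from the platform's annotation table. Of the probes, 30113 had 1 gene symbol, 8 had several and 17202 are unnamed here, and 30074 of the named matched a current gene table by gene number. A probe was kept with a detection p under 0.01 on at least 4 arrays, which left 20604 probes. For each gene the probe with the highest mean was used, giving 16480 genes or unnamed probes tested, 12445 of them named. Of 53 results named for the size of their change, each of 1 gene for 1 term, 0 had another probe past the threshold in the opposite direction. Some genes were named for several terms, and a gene with a single kept probe could not show such a conflict.

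For each gene limma fitted log2 BMP4 dose, log2 CHIR dose, their product and the square of each, with centred doses and empirical Bayes variances. The slopes are given over 4 doublings of BMP4 and 3 of CHIR at the mean of the other dose. With 1 array per combination there are no replicates. The p-values therefore measure the spread about the fitted dose surface, with 14 residual degrees of freedom and a prior of 3.11. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and all tests were two-sided. The number of arrays limits the precision. A fold against an array where a probe was not above background was taken against the higher of the probe's own signal and the lowest signal above background there, and is given as a lower bound.

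Of 31 gene lists, 30 had the 3 tested members required, and 267 of the 380 list genes were tested, 346 having a named probe. Lists were tested with camera at its preset correlation of 0.01, and the members past the threshold were counted over all genes and adjusted over the list alone. All 60 list calls over the 5 terms were lost with an estimated correlation, where the smallest adjusted p was 0.189. The slope of each list's mean was tested by permuting 1 dose within each level of the other, with 100000 resamples.

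The design, lists, named-gene rule and most alternatives were set before the data were examined. Named were the 8 genes of largest change each way for each slope and the 5 for the other terms, and in each list up to 4 members of smallest p. Genes of sex chromosomes used to check samples were left out. Alternatives were the background correction, scaling, offset, probe filter, probe rule, model, array weights, day tag, variance options, and leaving out single arrays or dose levels. In the fits without a dose level, doses were centred on the arrays left. This centring replaced one on all arrays after the values had been seen.

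The fits were tested on simulated data with changes of 1, 2 and 4 log2 units among 16480 genes. Noise was normal and independent around each gene's flat mean, and 1 term was changed at a time. The simulation held no correlation between genes and no misfit of the dose surface. Its shares of false calls therefore need not apply to the real data. The BMP4 slope recovered 80.6%, 95.5% and 100% of them, with 5.15% of its calls false. The CHIR slope recovered 86.6%, 100% and 100% (4.98% false), and the interaction 8.96%, 70.1% and 90.9% (3.42%). The BMP4 curvature recovered 91%, 100% and 100% (4.9%), and the CHIR curvature 89.6%, 98.5% and 100% (6.8%). Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.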

Results

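The series profiled HuES6 cells, an established human embryonic stem cell line, on Illumina bead arrays after 14 days of differentiation. Its title names the question as which fates follow from diverse doses of BMP and WNT signalling at induction. BMP4, a ligand of the BMP pathway, was given on the first day at 5 doses (0.25, 0.5, 1, 2 and 4 ng/ml). Each was crossed with 4 doses (0.25, 0.5, 1 and 2 µM) of the compound written CHIR00921 in the labels, called CHIR here. Each of the 20 combinations has 1 array and none has a replicate, so the number of arrays limits the precision of every value. The mean signal per array lay between 238.6 and 293.7, and 36.7% to 40.7% of the 47323 probes were above background. Over the genes tested, pairs of arrays correlated between 0.888 and 0.992. Values are normalized log2 signals, and a change is the one fitted over the whole dose range, with its standard error (SE).

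The means of heart muscle transcripts were high along a diagonal band of the dose grid and low where both doses were lowest or both highest. The mean of 18 sarcomere genes, which encode the contractile apparatus of heart muscle, was 10.54 at 0.25 ng/ml BMP4 with 2 µM CHIR and 9.68 at 4 ng/ml with 0.25 µM. It was 6.32 with both doses lowest and 5.71 with both highest. The pluripotency list had its highest mean, 9.18, with both doses lowest, and the endoderm and liver list, 10.85, at 0.25 ng/ml BMP4 with 0.5 µM CHIR. All pluripotency list results cover the 8 tested genes of 14. POU5F1 and NANOG are not among them, as each was above background on 3 arrays and failed the filter of 4. The blood list, whose HBZ and HBG1 encode embryonic and fetal globins, had its highest mean of 7.93 at 0.5 ng/ml with 0.5 µM. Toward the highest doses lay the highest means of the HOX groups 5 to 9, 9.11 at 2 ng/ml with 2 µM, and of the endothelial list, 7.79, and the fibroblast and matrix list, 11.1, both at 4 ng/ml with 2 µM. Of 16480 genes tested, 6039 passed limma's F test of the 5 dose terms together. With an additive model of the 2 doses, 2661 passed.

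**Figure D1:**
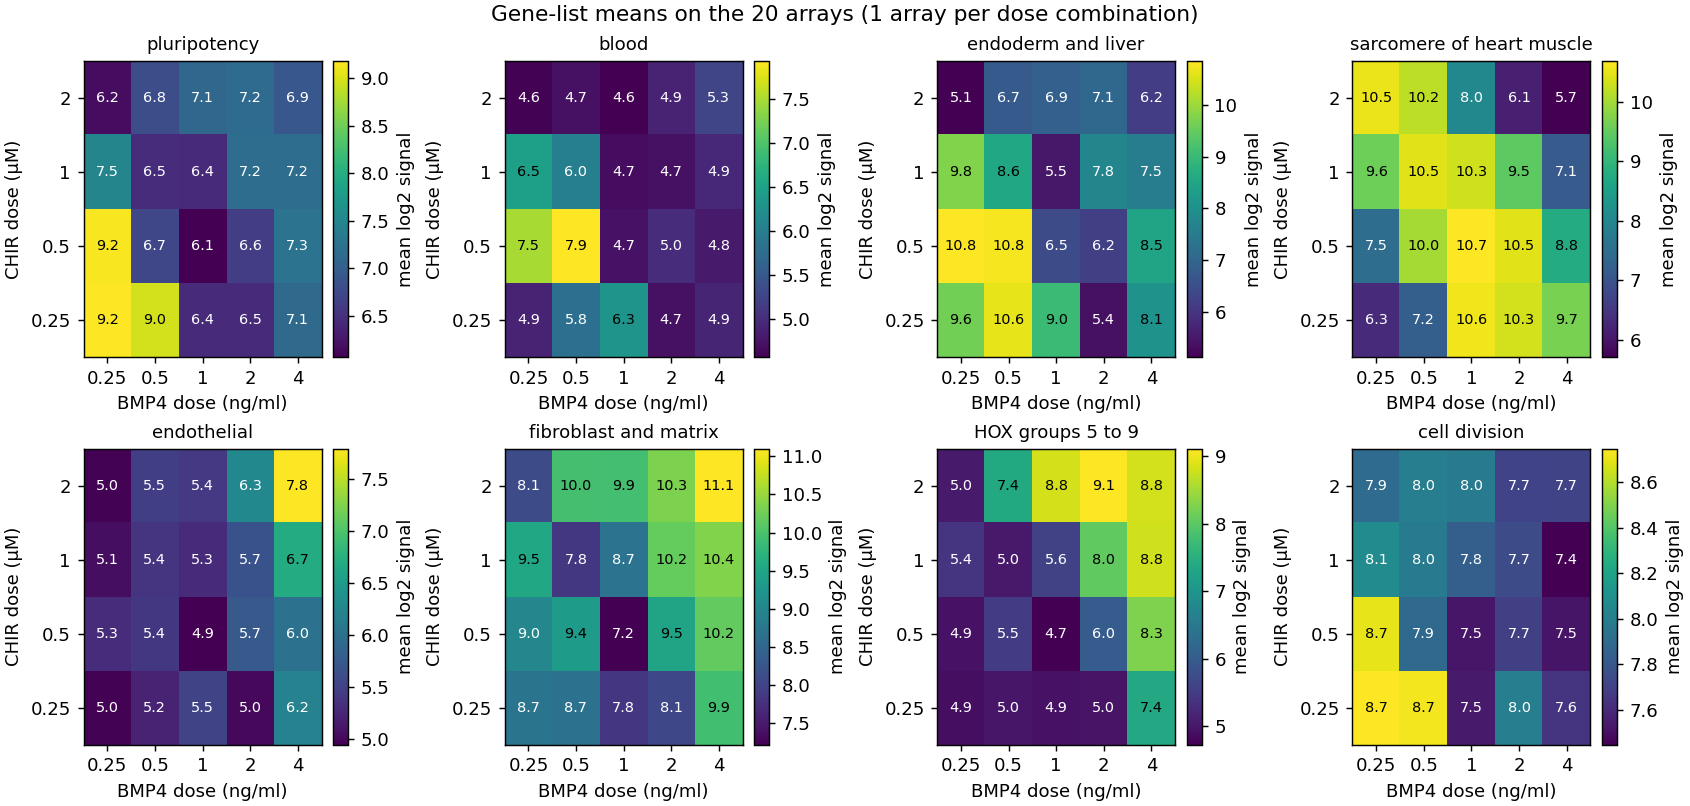
Mean normalized log2 signal of 8 gene lists on the 20 arrays, with the BMP4 dose (ng/ml) on the horizontal and the CHIR dose (µM) on the vertical axis. Each cell is 1 array, and each panel has its own colour scale. The sarcomere mean is 10.54 at 0.25 ng/ml BMP4 with 2 µM CHIR and 5.71 at 4 ng/ml with 2 µM.

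The BMP4 slope was largest for EGFL6, PRPH and HOXB8. EGFL6, a secreted protein with EGF-like repeats, rose by 5.50 log2 units (SE 0.83, adjusted p = 0.000298) at the mean CHIR dose. PRPH, the neuronal intermediate filament peripherin, rose by 5.47 (SE 1.08, adjusted p = 0.00217), and the homeobox gene HOXB8 rose by 5.32 (SE 0.80, adjusted p = 0.000302). SERPINE3, PLAT (tissue plasminogen activator), NPY (neuropeptide Y), STMN2 (a neuronal microtubule regulator) and FRZB (a secreted WNT antagonist) rose by 4.23 to 5.15. The EGFL6 probe was above background on 12 of the 20 arrays. At 2 µM CHIR its signal was at least 153-fold higher with 4 than with 0.25 ng/ml BMP4, a bound because the probe was not above background at the lower dose. GLDC, the glycine decarboxylase of mitochondria, fell by 3.49 (SE 0.32, adjusted p = 5.57e-06). LIN28A, an RNA-binding protein of stem cells, fell by 3.10 (SE 0.50, adjusted p = 0.000531). SPINK1, ZIC2, ALPL (alkaline phosphatase) and DLX5 fell by 2.84 to 3.59, and the globins HBG1 and HBZ fell by 2.91 and 2.81. The globin calls were kept in 4 and 5 of the 20 fits with 1 array left out, and probes of this gene family may share signal.

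All 7 tested members of the HOX groups 5 to 9 rose with BMP4, also adjusted over the list alone, with HOXC6 at 3.58 (SE 0.50) and HOXC8 at 3.97 (SE 0.62). The list passed limma's camera test (adjusted p = 9.33e-08), with adjusted p = 0.286 with an estimated correlation and a range of 6.97e-09 to 0.286 over the alternatives. Of the 17 cell division genes, 15 fell, and 16 adjusted over the list alone, among them the mitotic kinase gene BUB1 at -1.23 (SE 0.16) and the replication clamp gene PCNA at -0.82 (SE 0.14). For this list camera gave adjusted p = 4.92e-10, and adjusted p = 0.394 with an estimated correlation (2.62e-16 to 0.394 over the alternatives). The cell division mean was 8.70 to 8.75 on the 3 arrays of lowest dose product (0.25 ng/ml BMP4 with 0.25 or 0.5 µM CHIR and 0.5 ng/ml with 0.25 µM) and 7.45 to 8.07 on the 17 others. The pluripotency mean was 8.97 to 9.18 on these 3 arrays and 6.07 to 7.48 on the others. Without them, a choice made after the data were seen, 1 cell division gene fell for BMP4 and 0 adjusted over the list alone (7 at an unadjusted p under 0.05), and the median change was -0.36 against -0.76 with all arrays. In every fit without these arrays the doses stayed centred on all 20 arrays, and the slopes depend on that centring. Of 9 endothelial genes 7 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone; CLDN5, a tight junction protein, rose by 1.95 (SE 0.32) and KDR, a VEGF receptor, by 1.21 (SE 0.22). For this list camera gave adjusted p = 0.000348, and adjusted p = 0.286 with an estimated correlation (9.9e-07 to 0.286). In the fibroblast and matrix list 7 of 13 rose, 9 adjusted over the list alone, with POSTN at 3.20 (SE 0.59) and PDGFRA at 2.52 (SE 0.34). Camera gave adjusted p = 0.000348, and adjusted p = 0.565 with an estimated correlation (6.7e-06 to 0.565). In the epicardial and mesothelial list 5 of 9 rose, 7 adjusted over the list alone, with TCF21 at 2.84 (SE 0.64), and camera gave adjusted p = 0.000354, or adjusted p = 0.501 with an estimated correlation (6.42e-05 to 0.501). In the endoderm and liver list 3 of 12 fell, also adjusted over the list alone, namely FOXA1, FOXA2 and FOXA3, transcription factors of endoderm. Camera gave adjusted p = 0.000348, and adjusted p = 0.585 with an estimated correlation (5.36e-05 to 0.585). Without the same 3 arrays 5 genes of the HOX groups 5 to 9 rose (7 adjusted over the list alone), 1 endothelial gene (1), 2 of the fibroblast and matrix list (8) and 8 epicardial genes (8), and 3 endoderm and liver genes fell (4). The median changes were then 4.11, 0.63, 1.97, 3.99 and -2.64, against 3.32, 1.21, 1.29, 1.78 and -2.14 with all arrays.

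Most called targets of both pathways fell at day 14 with the BMP4 dose of the first day. Of 12 BMP pathway targets 4 fell and 1 rose, and 5 fell and 1 rose adjusted over the list alone. ID3 fell by 1.80 (SE 0.32) and ID1 by 1.75 (SE 0.34), both inhibitors of basic helix-loop-helix factors, while BMP4 itself rose by 0.92 (SE 0.25). Of 6 WNT pathway targets 4 fell, also adjusted over the list alone, among them LEF1 by 1.15 (SE 0.24) and AXIN2 by 0.88 (SE 0.24). Camera gave adjusted p = 0.0458 for the BMP list and 0.018 for the WNT list, and adjusted p = 0.585 and 0.394 with an estimated correlation (ranges 0.00699 to 0.585 and 9.8e-05 to 0.394). Without the 3 arrays of lowest product 5 BMP targets fell and 1 rose (7 and 1 adjusted over the list alone, median -0.918 against -0.345 with all arrays), and 2 WNT targets fell (3 and 1 higher adjusted over the list alone, -0.678 against -0.685). In all, 3263 genes passed the threshold for the BMP4 slope, 1629 higher and 1634 lower, or 49.9% higher, and with median scaling 40.3% of 2956 were higher. Without the 4 ng/ml arrays 1196 passed, and without the 0.25 ng/ml arrays 1484, with doses centred on the arrays left, a choice made after the values were seen. With the earlier centring on all arrays limma called 0 (1587 at an unadjusted p under 0.05) and 54.

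The CHIR comparison asked how day 14 transcripts followed the first-day dose of the compound. EGFL6 rose by 3.87 (SE 0.78, adjusted p = 0.00751) and HOXB8 by 3.60 (SE 0.76, adjusted p = 0.00945) at the mean BMP4 dose. MGP, a matrix protein that inhibits calcification, rose by 3.57 (SE 0.44, adjusted p = 0.000327). SERPINE3, HOXC8, PLAT and CPED1 rose by 3.05 to 3.40, and PRPH rose by 3.85 (SE 1.03, adjusted p = 0.0291), a call kept in 15 of the 20 fits with 1 array left out. SPINK1, a trypsin inhibitor, fell by 3.62 (SE 0.81, adjusted p = 0.0123). CGA, the common subunit of the glycoprotein hormones, fell by 2.72 (SE 0.56, adjusted p = 0.00806). LIN28A, ZIC2, ALPL, GLDC and the anterior homeobox gene OTX2 fell by 2.24 to 2.69. The ZIC2 call was lost without the array of 4 ng/ml BMP4 with 0.25 µM CHIR, and the call of APOA1, which fell by 2.33 (SE 0.70, adjusted p = 0.0496), was kept in 3 of 20 such fits.

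All 7 tested genes of the HOX groups 5 to 9 rose with CHIR, also adjusted over the list alone, and camera gave adjusted p = 9.27e-09, or adjusted p = 0.308 with an estimated correlation (2.57e-10 to 0.308 over the alternatives). Of 5 genes of the HOX groups 1 to 4, 3 rose with CHIR and 4 with BMP4, and 4 for either dose adjusted over the list alone, with HOXC4 at 2.24 (SE 0.41) for CHIR. For CHIR camera gave adjusted p = 0.000147 for this list, and adjusted p = 0.308 with an estimated correlation (0.000176 to 0.308). Of 9 trophoblast genes 2 fell with CHIR, CGA and TFAP2C, and 5 fell and 1 rose adjusted over the list alone. Camera gave adjusted p = 0.00231, and adjusted p = 0.308 with an estimated correlation (2.38e-06 to 0.308). Without the 3 arrays of lowest dose product limma called 0 trophoblast genes for CHIR (7 at an unadjusted p under 0.05, against 6 with all arrays), and 2 fell and 1 rose adjusted over the list alone. The median change stayed about as large, -0.82 against -0.95. For CHIR 5 genes of the HOX groups 5 to 9 then rose (7 adjusted over the list alone), 1 of the groups 1 to 4 (3), and 3 endoderm and liver genes fell (5). In the endoderm and liver list 4 of 12 fell, 7 adjusted over the list alone, with FOXA3 at -1.62 (SE 0.25). The camera test gave adjusted p = 4.1e-06, and adjusted p = 0.412 with an estimated correlation (5.28e-07 to 0.412). Camera also called the fibroblast and matrix list (adjusted p = 0.000127) and the epicardial list (0.0317) higher with CHIR. It called the cell division (0.00377), sarcomere (0.00629), pluripotency (0.0124) and neural (0.0317) lists lower. With an estimated correlation the adjusted p of these lists lay between 0.412 and 0.644. Of the 6 WNT pathway targets limma called 0 for CHIR (1 at an unadjusted p under 0.05), and 1 fell adjusted over the list alone, with camera adjusted p = 0.267. The CHIR slope passed for 1363 genes, 775 higher and 588 lower, or 56.9% higher, and with median scaling 76.8% of 1482 were higher. Leaving out 1 array gave 733 genes without 1 ng/ml BMP4 with 2 µM CHIR, 747 without 2 with 2, 2220 without 4 with 2, 808 without 0.5 with 0.25, 760 without 2 with 0.25 and 837 without 4 with 0.25, and without all arrays of 2 µM limma called 0 (2656 at an unadjusted p under 0.05).

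Named genes past both thresholds include EGFL6, HOXB8, PRPH and PLAT, higher with either dose, and GLDC, LIN28A, SPINK1 and ZIC2, lower with either. Of 1082 genes past both, 633 were higher with both, 448 lower with both and 1 opposite, against 76.6, 58.3 and 135 for independent lists. Across all genes, which are not independent replicates, the changes correlated at 0.873. Both slopes come from the same 20 arrays. With the arrays assigned at random to the dose combinations 100 times, the correlation lay between -0.807 and 0.833.

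**Figure D2:**
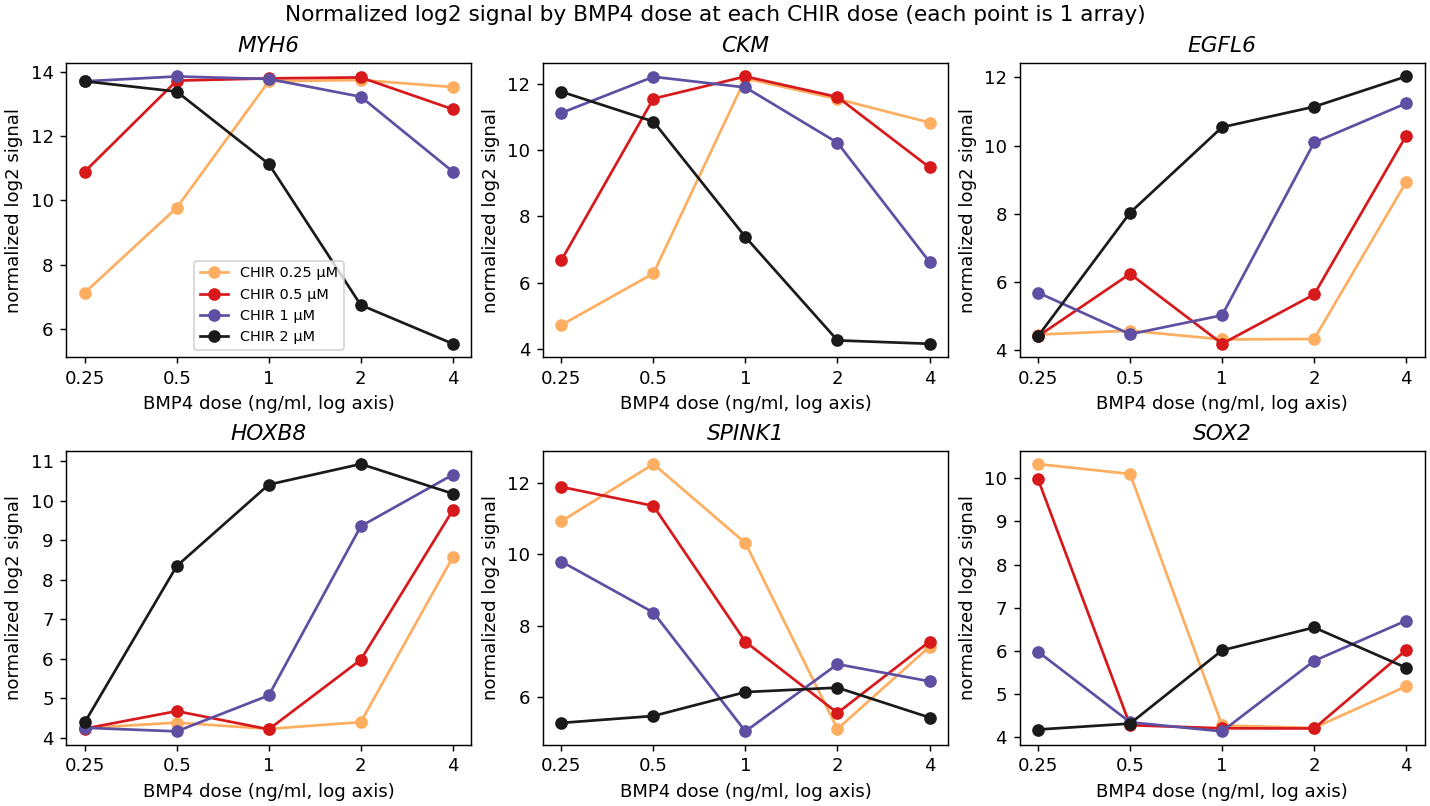
Normalized log2 signal of 6 genes against the BMP4 dose (ng/ml, log axis), with 1 line per CHIR dose. Each point is 1 array, without replicates. MYH6 is 7.13 at 0.25 and 13.52 at 4 ng/ml BMP4 with 0.25 µM CHIR, and 13.70 and 5.54 with 2 µM.

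The BMP4 response of heart muscle genes depended on the CHIR dose. MYH6, the alpha myosin heavy chain, was 84.2-fold higher with 4 than with 0.25 ng/ml BMP4 at 0.25 µM CHIR and 286-fold lower at 2 µM. Its interaction, the difference of the fitted BMP4 change between the highest and lowest CHIR dose, was -15.53 (SE 1.17, adjusted p = 3.29e-06), and probes of MYH6 and its paralog MYH7 may share signal. CKM (muscle creatine kinase, -16.13, SE 1.99), the adhesion molecule VCAM1 (-15.93, SE 2.27), TECRL (-15.01, SE 1.48) and the light chain MYL3 (-14.77, SE 1.71) had the other interactions furthest below 0. The opposite sign was found for KISS1 (kisspeptin, 7.62, SE 1.05, adjusted p = 0.000498), whose signal at 4 ng/ml BMP4 was at least 95.5-fold higher with 2 than with 0.25 µM CHIR. VTN (vitronectin, 9.29, SE 2.47), SOX2 (a pluripotency and neural factor, 8.97, SE 2.09) and ZIC2 (7.59, SE 1.75) shared that sign, but their calls were lost without the array of 0.25 ng/ml BMP4 with 2 µM CHIR. PITX1, at 8.27 (SE 2.81, adjusted p = 0.048), kept its call in 7 of 20 fits with 1 array left out.

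All 18 sarcomere genes had a negative interaction past the threshold, also adjusted over the list alone, with a median of -9.65. Camera gave adjusted p = 4.29e-21, and adjusted p = 0.259 with an estimated correlation (1.1e-30 to 0.259 over the alternatives). Without the array of 0.25 ng/ml BMP4 with 2 µM CHIR, 11 of the 18 passed. All 8 genes of the ventricular-associated list passed on both adjustments, with a median of -13.0 (camera adjusted p = 2.01e-10, or adjusted p = 0.259 with an estimated correlation, range 5.48e-15 to 0.259). Its members MYH7 and MYL3 are also in the sarcomere list. The atrial-associated list shares MYL7 with the sarcomere list and TBX5 with the cardiac transcription factors. Of 11 ion handling genes 7 passed, and 8 adjusted over the list alone, among them PLN (phospholamban) at -11.47 (SE 1.26), with camera adjusted p = 1.02e-06, or adjusted p = 0.292 with an estimated correlation (9.96e-10 to 0.292). Of 12 cardiac transcription factors 7 were negative, 9 negative and 1 positive adjusted over the list alone, with NKX2-5 at -14.26 (SE 2.14), and camera gave adjusted p = 0.000359, or adjusted p = 0.292 with an estimated correlation (4.57e-06 to 0.292). Of 11 hypoxia and glycolysis genes 6 were negative, 9 adjusted over the list alone, with BNIP3 at -6.58 (SE 1.25) and LDHA at -3.76 (SE 0.80), and camera gave adjusted p = 4.54e-05, or adjusted p = 0.292 with an estimated correlation (2.64e-07 to 0.292). In the atrial-associated list 2 of 6 were negative, 3 adjusted over the list alone, and in the fatty acid oxidation list 6 of 10, 7 adjusted over the list alone. Their camera adjusted p were 0.0275 and 0.000898, or adjusted p = 0.292 for each with an estimated correlation (0.00119 to 0.292 and 0.000383 to 0.292). On the positive side were 5 of 8 pluripotency genes, 7 adjusted over the list alone (camera adjusted p = 0.00101, or adjusted p = 0.32 with an estimated correlation, range 6.73e-05 to 0.32), and 6 of 9 trophoblast genes on both adjustments (camera adjusted p = 0.000898, or adjusted p = 0.292 with an estimated correlation, range 9.06e-08 to 0.292).

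The interaction passed for 3179 genes, 1504 positive and 1675 negative, or 47.3% positive, and with median scaling 29.1% of 3100 were positive. Leaving out 1 array gave 231 genes without 0.25 ng/ml BMP4 with 2 µM CHIR, 1889 without 2 with 2, 5320 without 4 with 2, 1744 without 0.5 with 0.25, 2030 without 2 with 0.25 and 2064 without 4 with 0.25. Without the 3 arrays of lowest dose product (0.25 ng/ml BMP4 with 0.25 or 0.5 µM CHIR and 0.5 ng/ml with 0.25 µM), a choice made after the data were seen, 182 genes passed. Of the 18 sarcomere genes 10 then passed, 16 adjusted over the list alone (median -8.02 against -9.65 with all arrays), and of the 8 ventricular-associated genes 2, 7 adjusted over the list alone (-7.67 against -13.0). Of 11 ion handling genes 1 passed, 3 adjusted over the list alone (-0.94 against -3.77), and of 6 atrial-associated genes 1, 3 adjusted over the list alone (-7.04 against -2.02). For cardiac transcription factors limma called 0 (4 at an unadjusted p under 0.05), with 4 negative adjusted over the list alone (-0.40 against -2.45), and for pluripotency 0 (3), with 1 positive adjusted over the list alone (0.69 against 3.15). On both adjustments it called 0 for fatty acid oxidation (1 at an unadjusted p under 0.05, median -0.35 against -2.00), hypoxia and glycolysis (2, -1.32 against -3.32) and trophoblast (2, 2.43 against 1.90), the last without a smaller median. It also called 0 on both for cell division (1 at an unadjusted p under 0.05), where 4 of 17 were positive with all arrays and the median changed sign (-0.34 against 1.01), and for the amnion-associated list (2), where 3 of 8 were positive (1.5 against 1.56). For surface epithelium it called 0 (2), with 1 adjusted over the list alone, against 3 of 8 with all arrays (1.20 against 1.48), and for endoderm and liver 1, with 3 adjusted over the list alone, against 3 of 12 (6.28 against 4.27).

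Curvature compares the ends of a dose range with its middle, fitted as 1 value over all levels of the other dose. MYH7 (-2.56, SE 0.41, adjusted p = 0.0215) and the atrial light chain MYL7 (-2.31, SE 0.34, adjusted p = 0.0173) had a negative BMP4 curvature, the middle above the ends, as did LIMS2 and ME1. At 2 µM CHIR the sarcomere mean was nonetheless highest at the lowest BMP4 dose (10.54). WNT6 (0.95, SE 0.11, adjusted p = 0.00152), LRRC3B, CA12 and TENT5A were higher at the ends, while COL15A1, also of positive curvature (1.23, SE 0.23, adjusted p = 0.0496), was higher toward the highest doses only. For CHIR, MYH6 was highest in the middle (-2.49, SE 0.35, adjusted p = 0.0185) and LYRM2 at the ends (0.62, SE 0.09, adjusted p = 0.0185). All 18 sarcomere genes had a negative BMP4 curvature adjusted over the list alone and 2 over all genes, with camera adjusted p = 2.53e-15, or adjusted p = 0.192 with an estimated correlation (1.36e-20 to 0.192). Over all genes limma called 14 for BMP4, 10 positive and 4 negative, and 2 for CHIR, 1 of each sign, with 4177 and 2205 at an unadjusted p under 0.05. With median scaling the CHIR curvature passed for 141 genes, 96.5% of them positive against 50% in the main setting. Whichever array was left out, the WNT6 call was kept, as 1 of the 9 named for BMP4 against 0 of the 2 for CHIR. With 1 array left out, taken from 0.25 to 4 ng/ml BMP4, the BMP4 curvature passed for 2265, 18, 1507, 46 and 2792 genes at 2 µM CHIR, for 2, 9, 1, 12 and 7 at 1 µM, for 9, 30, 2, 13 and 6 at 0.5 µM and for 288, 883, 4, 10 and 1 at 0.25 µM. In the same order the CHIR curvature passed for 3, 3, 2, 1 and 347 genes at 2 µM, for 0, 0, 3, 2 and 2 at 1 µM, for 3, 2, 4, 0 and 0 at 0.5 µM and for 4, 2, 3, 0 and 0 at 0.25 µM, and limma's counts of 0 had 1714 to 2203 genes at an unadjusted p under 0.05.

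The other lists are given here for the BMP4 slope. In the blood list CD34 rose and RUNX1, HBZ and HBG1 fell, of 7 tested (1 rose and 5 fell adjusted over the list alone). Of 9 smooth muscle genes SMTN and ACTG2 rose while MYLK, CNN1 and 1 other fell, the same numbers as adjusted over the list alone. In the cartilage list 3 of 8 rose, among them SOX6 at 2.05 (SE 0.36), and 2 fell, with COL9A1 at -1.91 (SE 0.29), and 4 and 2 adjusted over the list alone. The neural list had STMN2 higher and 4 of 8 lower, 5 adjusted over the list alone, and the neural crest list 1 higher and 2 lower of 4 on both adjustments. In the kidney list 1 of 5 rose and 3 fell, 2 and 3 adjusted over the list alone. DLL1 was the paraxial mesoderm gene that fell, of 5 (2 adjusted over the list alone), and ACTA1 the skeletal muscle gene that fell, of 4, on both adjustments. Of the amnion-associated list 1 of 8 rose and 2 fell on both adjustments, and of the surface epithelium list 3 of 8 fell, 4 adjusted over the list alone. PDK4 alone rose of 10 fatty acid oxidation genes on both adjustments, and of 6 atrial-associated genes limma called 0 on both (1 at an unadjusted p under 0.05). Of 12 stress response genes ATF3 fell, and of 9 housekeeping genes B2M rose by 0.98 (SE 0.16) and YWHAZ fell by 0.33 (SE 0.10), the same as adjusted over the list alone. HOXC13 was the only tested gene of the HOX groups 10 to 13, with -0.33 (SE 0.17, adjusted p = 0.203), so that list was not tested. On the 3 arrays of lowest product the neural mean was 7.83 to 7.95 against 6.24 to 7.07 on the 17 others, the kidney mean 6.22 to 6.77 against 5.11 to 6.12, the paraxial mesoderm mean 6.30 to 6.33 against 4.96 to 5.77 and the surface epithelium mean 8.79 to 8.86 against 7.45 to 8.77. Without these arrays the neural list had 2 higher and 0 lower (2 and 2 adjusted over the list alone, 5 at an unadjusted p under 0.05, median -0.26 against -1), and the kidney list 1 and 0 (1 and 1, 2 unadjusted, -0.09 against -0.47). The surface epithelium list then had 2 lower (3), paraxial mesoderm 1 lower (1), and the amnion-associated list 0 on either side (2 lower adjusted over the list alone, 4 unadjusted). Blood then had 5 lower (6), fatty acid oxidation 2 lower (1 higher and 5 lower) and the atrial-associated list 1 higher (2 higher and 1 lower). For the BMP4 slope camera gave these other lists adjusted p between 0.0929, for the blood and the neural list, and 1, for housekeeping.

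List means were also tested without a model of the spread, by permuting BMP4 doses within each CHIR dose and the reverse. Means rose with BMP4 for the HOX groups 5 to 9 (3.12 over the range, higher at the highest dose in 4 of 4 CHIR doses), the endothelial list (1.40, 4 of 4), the epicardial list (1.74, 4 of 4) and the HOX groups 1 to 4 (1.06, 4 of 4). They fell for cell division (-0.77, the list whose mean was highest on the 3 arrays of lowest product), WNT pathway targets (-0.65) and BMP pathway targets (-0.58), each lower in 4 of 4. The two-sided permutation p lay between 7e-05 and 0.0098 and the adjusted p between 0.0017 and 0.042. These counts compare only the highest with the lowest dose. At 2 µM CHIR the epicardial mean peaked at 0.5 ng/ml BMP4 (8.34, and 6.88 at 4 ng/ml). The HOX groups 1 to 4 peaked there at 1 ng/ml (7.23, and 6.91) and the groups 5 to 9 at 2 ng/ml (9.11, and 8.82). At 1 µM the epicardial mean peaked at 2 ng/ml (8.66, and 7.76). At the other CHIR doses these means peaked at 4 ng/ml. The falling means were not always lowest at 4 ng/ml either. The WNT mean was lowest at 1 ng/ml with 0.25 and 0.5 µM CHIR (7.34 and 7.22) and at 2 ng/ml with 2 µM (6.95). The BMP mean was lowest at 1 ng/ml with 2 µM (7.58, and 8.06 at 4 ng/ml). The cell division mean was lowest at 1 ng/ml with 0.25 µM (7.54) and at 2 ng/ml with 2 µM (7.71). At the remaining CHIR doses the falling means were lowest at 4 ng/ml. With CHIR the HOX groups 5 to 9 (2.38, permutation p = 6e-05, adjusted p = 0.0018) and 1 to 4 (1.06, permutation p = 0.00023, adjusted p = 0.00345) rose, each in 5 of 5 BMP4 doses. The trophoblast mean fell with CHIR (-0.83, permutation p = 0.0043, adjusted p = 0.0428), but was higher at the highest CHIR dose in 1 of 5 BMP4 doses. Of 30 lists 7 thus passed for BMP4 and 3 for CHIR. Leaving out the array of 0.25 ng/ml BMP4 with 2 µM CHIR, 4 with 1, 0.25 with 0.5 or 0.5 with 0.5 left 4 for BMP4, and without 2 with 0.25 there were 5 for CHIR.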

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

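Of the tests in this part, those on random assignments of the arrays, on array brightness as a covariate, without the 3 arrays of lowest dose product and on the product of the doses were chosen only after the results were seen.

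The results below were singled out because the effect of BMP4 differed with the CHIR dose, by limma's test of the interaction term. That term passed for 3179 genes. Negative medians over a list were found for sarcomere genes (-9.65), the ventricular-associated list (-13), ion handling (-3.77), hypoxia and glycolysis (-3.32), cardiac transcription factors (-2.45), the atrial-associated list (-2.02) and fatty acid oxidation (-2). Positive medians were found for endoderm and liver (4.27), pluripotency (3.15), trophoblast (1.9), the amnion-associated list (1.56), surface epithelium (1.48) and cell division (1.01). Without the 3 arrays of lowest dose product the cell division median changed sign, to -0.34. By camera all these lists passed, and with an estimated correlation none did (0 lists, 3 unadjusted, smallest adjusted p = 0.259). For endoderm and liver camera gave adjusted p = 0.00581, or adjusted p = 0.51 with an estimated correlation (0.000194 to 0.51 over the alternatives), and for cell division 0.00411, or adjusted p = 0.504 with an estimated correlation (0.000132 to 0.504). Limma's fry test lost these 2 calls as well (adjusted p = 0.0916 and 0.0612). The amnion-associated list had 0.00946, or adjusted p = 0.343 with an estimated correlation (0.000594 to 0.343), and surface epithelium 0.0125, or adjusted p = 0.292 with an estimated correlation (0.00852 to 0.292). Single genes were VTN (9.29), SOX2 (8.97), PITX1 (8.27), KISS1 (7.62) and ZIC2 (7.59) on the positive side. On the negative side were CKM (-16.13), VCAM1 (-15.93), MYH6 (-15.53), TECRL (-15.01) and MYL3 (-14.77).

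The arrays were also assigned at random to the dose combinations, 100 times with the real assignment included. For the BMP4 slope 1 assignment gave as many genes, the real one with 3263, and the highest other gave 23. For the CHIR slope it was 1 (1363 against 1), for the interaction 1 (3179 against 1733) and for any dose term 1 (6039 against 2788). These counts argue against arrays that bear no relation to the doses. Random assignment removes the slopes together with the interaction, so it cannot test the interaction count given the slopes. For the BMP4 curvature 2 assignments gave as many as the real 14 and for the CHIR curvature 4 gave as many as the real 2. The highest others, 1494 and 1460, lie far above these counts, so the curvature counts are not taken as beyond chance. Assignments that call so many genes may point to a structure of the samples, which was not tested for them.

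The interaction of heart muscle genes held for all 18 sarcomere genes with the array's mean signal as a covariate and for 18 with median scaling, which argues against array brightness and normalization between arrays. A wrong array stays open, since 11 passed without the array of 0.25 ng/ml BMP4 with 2 µM CHIR and at least 17 without any other. As a hypothesis, BMP4 and CHIR may act along 1 shared dose axis: 8 levels of the product of the doses explained 80.9% of the variance between arrays over all genes, against 18.2% for their ratio and at most 57.8% for 99 random groupings. Leaving out single arrays gave 79% to 83.5%. No other biological explanation was tested.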

How the results depend on the processing

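Of the tests in this part, those without the 3 arrays of lowest dose product, those with array brightness as a covariate, and the centring of doses in the fits without a dose level were chosen only after results were seen. Without replicates, leaving out arrays or dose levels is the main check, and probes near background limit folds to bounds. Over 245 gene results, 8120 fits kept direction and side of the threshold, 1932 no longer passed and 12 reversed. Over 150 list results, 481 stayed, 88 were lost and 31 gained. A beadchip block was not run, as the files used here name none, and additive models give no interaction. The cause was not tested for any value below.

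Counts of genes that moved over 1.5 times are given here, with counts at an unadjusted p under 0.05 beside limma's 0. The BMP4 curvature (14) passed for 7 without background correction, 65 with the authors' values, 6 with offset 50, 7 without a filter, 3 with probes detected on all 20 arrays and 85 with the mean of a gene's probes. The CHIR curvature (2) passed for 17 without background correction, 141 with median scaling, 26 without a filter, 4 with probes detected on all 20 arrays and 1 with the day tag. The interaction passed for 2034 without a filter. The CHIR slope passed for 890 with probes detected on all 20 arrays, 614 in the additive model and 900 with the day tag, and any dose term for 2661 in the additive model. Dose levels as factors gave 2017 for the BMP4 slope, 395 for the CHIR slope and 0 for both curvatures (2198 and 1522). Array quality weights gave 5008, 3419, 4991, 4863 and 1755 for the BMP4 slope, CHIR slope, interaction, BMP4 curvature and CHIR curvature.

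Without BMP4 0.25 ng/ml, the BMP4 slope passed for 1484, the interaction for 222 and the curvatures for 0 (2456) and 0 (2288). Without 0.5 ng/ml, the CHIR slope passed for 509, the interaction for 1105 and the curvatures for 47 and 0 (1329). Without 1 ng/ml, the CHIR slope passed for 767 and the curvatures for 0 (1612) and 0 (2123). Without 2 ng/ml, the slopes passed for 1681 and 243, the interaction for 364 and the curvatures for 6 and 0 (1543). Without 4 ng/ml, the BMP4 slope passed for 1196 and the curvatures for 0 (936) and 0 (2641). Without CHIR 0.25 µM, the slopes passed for 2069 and 199, the interaction for 164 and the curvatures for 3 and 0 (806). Without 0.5 µM, the slopes passed for 1402 and 341, the interaction for 1578 and the curvatures for 0 (1136) and 0 (1614). Without 1 µM, the slopes passed for 1671 and 46, the interaction for 761 and the curvatures for 1 and 0 (1236). Without 2 µM, the CHIR slope passed for 0 (2656), the interaction for 667 and the curvatures for 4584 and 0 (727). With doses centred on all arrays, as first run, the BMP4 slope passed for 54 (1969) without 0.25 ng/ml and 0 (1587) without 4 ng/ml, and the CHIR slope for 0 (858) without 0.25 µM and 0 (1057) without 2 µM. That centring also gave over 1.5 times more or fewer for the CHIR slope without 2 ng/ml (123), 0.5 µM (623) and 1 µM (524), and for the BMP4 slope without 0.25 µM (1243) and 2 µM (1884). Without the 3 arrays of lowest product, with doses centred on all arrays, the slopes passed for 2026 and 750, the interaction for 182 and the curvatures for 72 and 0 (1444).

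Leaving out single arrays gave 2310 to 3772 genes for the BMP4 slope, 733 to 2220 for the CHIR slope, 231 to 5320 for the interaction, 1 to 2792 for the BMP4 curvature and 0 to 347 for the CHIR curvature. List means passed for 4 to 8 lists with BMP4 and 2 to 5 with CHIR. With an estimated correlation camera called 0 lists for each of the 5 terms (3, 4, 3, 4 and 0 unadjusted), and fry called 0 for the CHIR curvature (3 unadjusted).

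The 12 reversed values did not pass the threshold. Without BMP4 0.25 ng/ml the BMP4 slopes of TFAP2C, VGLL1 and WNT6 were 0.099, 0.31 and 0.39, and without 0.5 ng/ml that of WNT6 was 0.054. The BMP4 slope of MYH7 was 0.0071 without 2 ng/ml, 0.90 without 4 ng/ml and 0.66 without CHIR 2 µM, and that of CNN1 was 0.087 without 4 ng/ml. Without the 3 arrays of lowest product EMX2 had 0.14 for BMP4, 0.10 for CHIR and -0.29 for the interaction, and HAND2 had -0.10 for CHIR.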

Other observations

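Of the tests in this part, that of a faulty GAPDH probe was set beforehand, and all others, on GAPDH, the day tags and the pluripotency transcripts, were chosen only after the results were seen. POU5F1, NANOG, EOMES, TBXT and PAX6 were chosen after their values were seen.

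Along the product of the doses, gene groups peaked in an order. The pluripotency mean was highest at a product of 0.0625 (9.18), the endoderm and liver mean at the next level (10.74), the blood mean at 0.25 (6.90) and the sarcomere mean at 0.5 (10.51). The atrial-associated mean was highest at 1 (8.31) and the ventricular-associated mean at 0.5 (11), and both lists share members with the sarcomere list. Epicardial genes followed at 2 (8.46), the HOX groups 5 to 9 at 4 (8.96), and endothelial genes (7.79) and fibroblast and matrix genes (11.1) at 8. Each level holds 1 to 4 arrays, and this order was read from the values without a test.

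The 3 arrays of lowest product (0.25 ng/ml BMP4 with 0.25 or 0.5 µM CHIR and 0.5 ng/ml with 0.25 µM) were the only arrays with POU5F1, EOMES, TBXT and PAX6 above background. EOMES and TBXT encode T-box factors of early mesoderm and endoderm, and PAX6 a factor of neural tissue and eye. Their mean levels there were 6.61 (SD 0.032) for POU5F1, 7.17 (SD 0.24) for EOMES, 5.01 (SD 0.15) for TBXT and 6.41 (SD 0.51) for PAX6, over 3 arrays of different doses. The highest levels on the 17 other arrays were 4.72, 4.59, 4.49 and 4.45. NANOG was also above background only on these 3 arrays, at 5.03 (SD 0.15) against up to 4.80 on the others. NANOG and TBXT lay close to background there, where the lowest signals above background were 4.74 to 4.82.

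For these pluripotency transcripts at the lowest doses, right day tags with samples not all of day 14 are argued against: POU5F1 had a detection p of 0.581 on the array tagged day 0, while 3 of the 9 arrays tagged days 1 to 3 detected it. That array had a sarcomere mean of 10.54. In the order of the titles the tags run from 0 through 1, 2, 3, 4, 5, 6 and 8 and then begin again at 1. As a hypothesis, undifferentiated cells may have remained at the lowest doses, which stays open. Of 5 pluripotency genes that failed the filter of 4 arrays, POU5F1 and NANOG were detected on all 3 arrays of lowest product. PRDM14, UTF1 and FGF4 were detected on 0 arrays at any dose, so their absence there cannot count against the hypothesis. Any gene detected only on these 3 arrays must fail that filter. The mean of the 8 tested pluripotency genes was 8.97 to 9.18 there and 6.07 to 7.48 on the 17 others. That difference is the pattern to be explained and does not decide its cause. The tag passed limma's threshold for 0 genes alone (1609 at an unadjusted p under 0.05) and 0 beside the dose terms (806).

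GAPDH, a glycolytic enzyme often used as a reference gene, ranged from 11.93 at 1 ng/ml BMP4 with 2 µM CHIR to 13.47 at 1 ng/ml with 0.5 µM, or 2.91-fold. Scaling between arrays is argued against, as GAPDH moved by 1.48 log2 units without it, and a faulty probe is argued against, as each of 3 GAPDH probes moved by at least 1.54. The mean of the 8 other housekeeping genes moved by 0.265, which leaves normalization between arrays undecided by that value, since single members moved about as much as GAPDH or more (SDHA by 2.32, B2M by 2.31, PPIA by 1.63 and ACTB by 1.44). As a hypothesis, GAPDH may follow the other glycolysis genes: over 20 arrays it correlated with the hypoxia and glycolysis list at r = 0.937 (rho 0.92, 0.942 without the 2 farthest arrays). It correlated as closely with the sarcomere list (r = 0.933, rho 0.935, 0.909 without the 2 farthest), so the relation is not specific to glycolysis. For the 2 relations computed, each permutation p and adjusted p was 1e-05, the smallest these permutations can give.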
